A study of Rattus norvegicus with 6 samples.

How the data were processed

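RNA was measured by sequencing of poly(A)-enriched libraries from rat facial nerve tissue taken on day 14 after injury. There were 3 libraries of the injury model, called FNI, and 3 of injured nerve given the treatment called C-Gel-light. Groups were taken from the treatment labels of the samples and replicate numbers from the sample titles. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Each library carried a batch label of its own, 1 to 3 for C-Gel-light and 4 to 6 for FNI, in the order of the replicates. The labels do not say whether this marks a processing batch or only a sample. If it marks a batch, differences between batches within a group are part of the spread the test uses, but no batch held both groups, so a batch term could not be fitted and batch and group cannot be told apart.

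The authors deposited whole-number counts per Ensembl gene ID, not normalized, for 30562 IDs. FastQC 0.11.9, fastp 0.22.0, STAR 2.4.2a, RSEM 1.2.29, edgeR 3.28.1 and the genome build mRatBN7.2 were named per the submitters' processing notes, which gave no role or order for them. If RSEM made the counts, they are estimates rounded to whole numbers, and reads shared by similar genes were divided between them. The authors also deposited FPKM values per library. In each library the deposited FPKM equalled the count times a constant, divided by the column total and by a gene length, which was a whole number within 0.01 for 100% of the 22044 genes with a count. The FPKM values were therefore a rescaling of the counts by library totals and length, not a separate measurement. Of these lengths 38.5% were multiples of 3, and their median over the tested genes was 2945 bases.

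Total counts ran from 22957382 in FNI replicate 3 to 28997855 in C-Gel-light replicate 1. Genes were kept with the filterByExpr function of edgeR at its minimum count of 10, which left 15581 genes holding at least 99.9% of the counts of each library. Counts were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, robust dispersions, group as the only term and a two-sided Benjamini-Hochberg adjusted p under 0.05. Fold changes are C-Gel-light over FNI. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values use TMM-scaled library sizes, and log2 CPM used a prior count of 2. Single values per library were compared by two-sided exact permutation tests, whose smallest possible p for 3 against 3 libraries is 0.1. Intervals at 95% on pooled counts, and the limit of 3 counts over a group used where a group had 0 counts, cover counting error only.

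No pair of libraries of a group was alike within counting noise. Over genes with at least 20 counts in the pair, the chi-square per degree of freedom was 79.8 to 175.1 between C-Gel-light libraries. Between FNI libraries it was 27 to 48.8. The median SD of log2 CPM within a group was 0.21 with C-Gel-light and 0.17 in FNI. The test used the same dispersion per gene for both groups.

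The test was tried on simulated counts for C-Gel-light against FNI over 15581 genes, with 50 genes changed at each size. It recovered 6% at 1.5-fold, 52% at 2-fold, 78% at 4-fold and 94% at 8-fold. Of its calls in that simulation 9.4% were false, above the nominal level, against 29.5% with DESeq2, 25.3% with the edgeR exact test and 7.4% with limma-voom. A simulation with no change gave 0 calls by the quasi-likelihood test. Far fewer genes were changed in the first simulation than the 2301 (14.8%) called in the data. An adjusted threshold is stricter when few genes change, so these recovery rates and false shares need not hold in the data.

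The files do not pair the IDs with gene names. The RefSeq gene table meant for names (GRCr8) held 0 Ensembl IDs, so none of the 30562 IDs could be matched. The 42 gene lists fixed before the data were examined, among them Schwann cell, macrophage and other cell type markers, could therefore not be tested, nor could the genes meant to be named by symbol. The rule for named genes, also fixed then, took those with the largest fold change in each direction among genes past the threshold, with a mean log2 CPM of at least 1 and no overlap between the groups. It was applied here without its condition on symbols, to 2 IDs per direction.

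The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE and upper quartile factors, library totals, other filters and thresholds, no robust dispersion, the replicate number as a block, limma with a trend on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out each library. The edgeR exact test, cyclic loess scaling, the removal of genes that may share reads or that vary with them and the removal of the 100 most abundant genes were added after seeing the data, as was the choice of 4-fold as a size to count.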

Results

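Gene expression was measured in rat facial nerve tissue on day 14 after injury, in 3 libraries of the injury model (FNI) and 3 libraries of injured nerve given C-Gel-light. The series title ties this treatment to a hydrogel holding Chlorella, a green alga, which releases oxygen in light. Total counts were 28997855, 27236996 and 25048554 in C-Gel-light replicates 1 to 3 and 25841659, 23180193 and 22957382 in FNI replicates 1 to 3. The mean was 27094468 ± 1978505 against 23993078 ± 1604790 (SD, n = 3 per group; two-sided exact permutation p = 0.2). A count was found for 19147 ± 161 genes with C-Gel-light and 19202 ± 144 genes in FNI (SD, n = 3; exact permutation p = 0.7). At 1 CPM or more by library totals, without TMM factors, there were 13878 ± 228 genes against 14225 ± 71 (SD, n = 3). By this measure every C-Gel-light library lay below every FNI library, with an exact permutation p of 0.1, the smallest possible. Uninjured nerve, hydrogel alone and light alone were not analysed here, so the comparison is of the whole treatment with injury alone.

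The 6 libraries separated by group. The first principal component of log2 CPM held 57.5% of the variance. Its scores were 37.4 to 51.8 for C-Gel-light and -50.1, -27.5 and -58.7 for FNI replicates 1 to 3. Of the FNI libraries, replicate 2 thus lay nearest to C-Gel-light. The second component held 12.4% and set C-Gel-light replicate 2, at 40.4, apart from the other libraries, which lay between -25 and 12.7. The 10 most abundant genes of each library held 19.2% ± 2.2 of the counts with C-Gel-light and 13% ± 1.7 in FNI (SD, n = 3), a difference of 6.3 percentage points. The 100 most abundant genes held 35.3% ± 3.3 and 27.5% ± 2.1. In both measures every C-Gel-light library lay above every FNI library, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. The TMM factors, which correct for such differences, were 0.866, 0.903 and 0.983 for C-Gel-light replicates 1 to 3 and 1.083, 1.054 and 1.139 for FNI replicates 1 to 3.

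**Figure D1:**
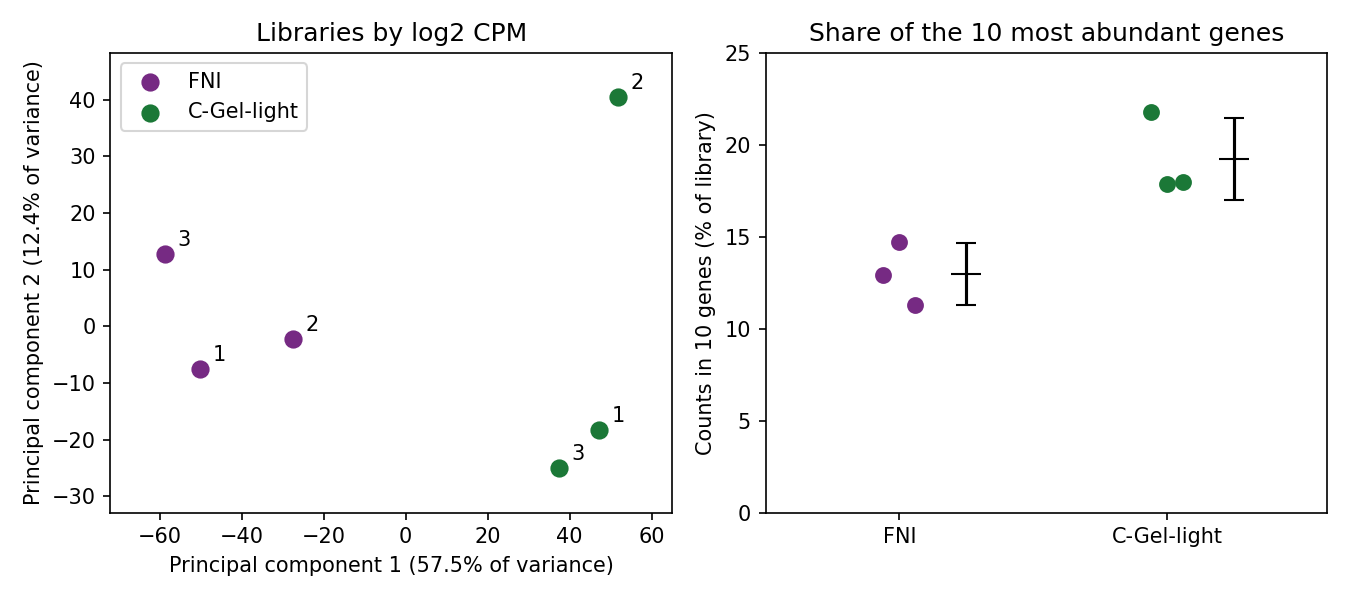
Left, scores of the 6 libraries on the first and second principal components of log2 CPM, with replicate numbers beside the points. Right, the percentage of each library's counts held by its 10 most abundant genes, with points for libraries and bars for the mean ± SD (n = 3); the C-Gel-light libraries lie between 17.9% and 21.8% and the FNI libraries between 11.3% and 14.7%.

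The design asks which genes treatment of the injured nerve raised or lowered. Of 15581 genes tested, 2301 (14.8%) differed between the groups by the quasi-likelihood test of edgeR at an adjusted p under 0.05. Of these 1101 were higher and 1200 lower with C-Gel-light. The median change was 1.8-fold among the genes that rose and 2.01-fold among those that fell. In all 2301 the values of the groups did not overlap, which is largely what a call at this threshold needs with 3 libraries per group. No overlap was found for 6086 (39.1%) of the tested genes. For any single gene chance gives 10%, but genes can vary together, so this share is no test of chance. The balance of rises and falls rests on the correction for composition: 47.8% of the changed genes were higher with TMM factors, but 16.4% with library totals alone (645 higher, 3292 lower), a scaling that moved the median log2 fold change of the tested genes to -0.26. Without C-Gel-light replicate 1 or 2 the test called 1204 or 1153 genes, and without FNI replicate 1 or 3 it called 797 or 849.

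Large changes were more often falls than rises. A change of at least 4-fold was found for 244 genes that fell and 98 that rose, and one of at least 8-fold for 102 and 23. Under 2-fold, 599 genes fell and 678 rose. Among the most abundant 20% of genes, 16 fell and 13 rose at least 4-fold. The genes that fell were less abundant, with a median of 21.9 CPM against 44.8 CPM for those that rose. Without FNI replicate 1, 2 or 3 the genes that rose at least 4-fold numbered 45, 151 or 41, and without C-Gel-light replicate 2 the rises and falls of this size numbered 50 and 157.

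With TMM factors, though not with library totals, the most abundant genes were more often higher than lower. In the 10% of tested genes that were most abundant, with a median of 190 CPM, 255 of the 382 changed genes (66.8%) were higher with C-Gel-light. In the 10% that were least abundant, with a median of 0.7 CPM, 36 of 98 (36.7%) were higher. With library totals these shares were 33.3% and 24.3%, so that falls then led in both. Among the least abundant the share was 20%, 17.2%, 21.1% and 18.2% without C-Gel-light replicates 1 and 2 and FNI replicates 1 and 3. These shares rest on only 40, 29, 19 and 22 changed genes. The share was 29.2% of 48 without C-Gel-light replicate 3 and 41.5% of 65 without FNI replicate 2. Among the most abundant it was 55% and 59.3% without FNI replicates 1 and 3, and 65.7% to 72.2% without each other library. Limma-voom gave 67.2% among the most abundant, and 53.3% with cyclic loess.

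**Figure D2:**
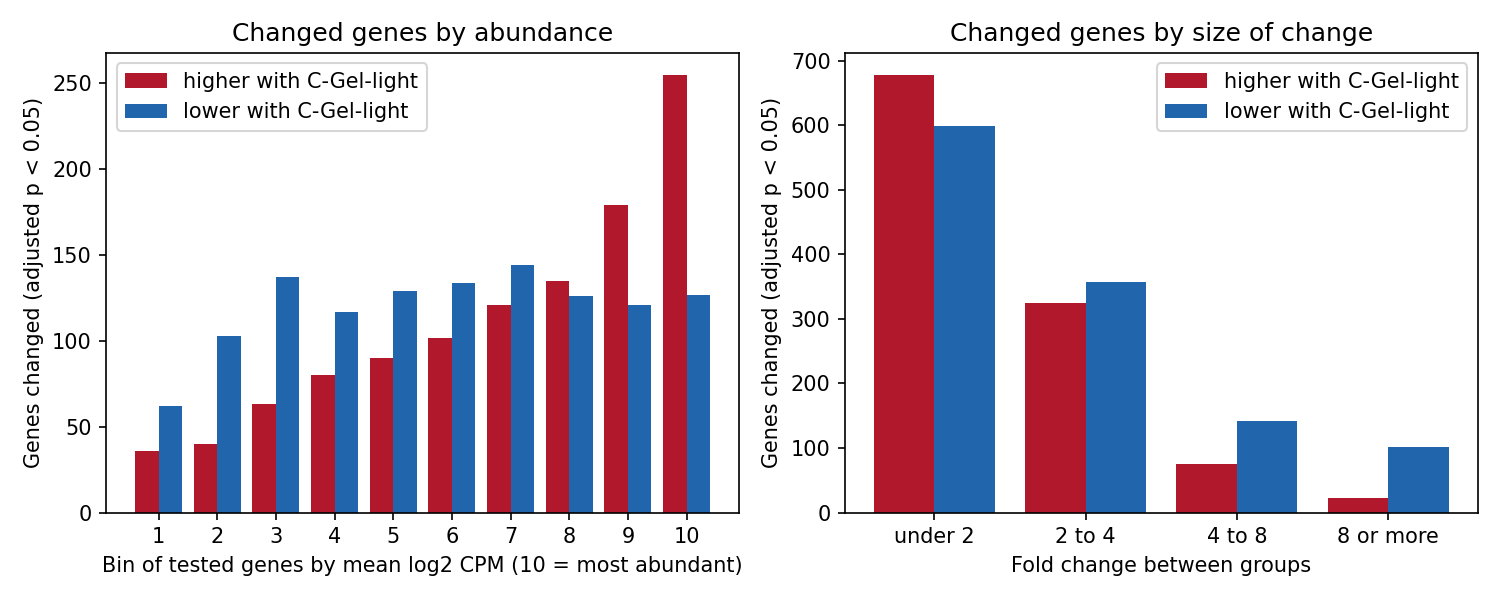
Left, genes changed at an adjusted p under 0.05 in 10 equal bins of the tested genes, ordered by mean log2 CPM. Right, the same genes by the size of their fold change. Red bars count genes higher and blue bars genes lower with C-Gel-light under TMM scaling; in the most abundant bin 255 were higher, a lead that library totals turn into one of falls, and at 8-fold or more 102 were lower and 23 higher.

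The files do not pair the gene IDs with names, so the genes with the largest changes are given by ID. ENSRNOG00000045554 rose from 1.22 ± 1.01 CPM in FNI to 34.2 ± 15.1 CPM with C-Gel-light (SD, n = 3), a log2 fold change of 4.82 (SE 0.67, adjusted p = 0.0094 by edgeR). ENSRNOG00000004614 rose from 0.279 ± 0.146 to 7.19 ± 5.82 CPM, a log2 fold change of 4.66 (SE 0.75, adjusted p = 0.013 by edgeR). Without FNI replicate 2 the first was 5.57, and without C-Gel-light replicate 2 the other was 3.77. Both were higher in each C-Gel-light library than in any FNI library, as the rule that chose them required.

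ENSRNOG00000009160 was nearly absent after treatment. It had 607, 556 and 190 counts in FNI replicates 1 to 3 and 2, 0 and 0 in the C-Gel-light libraries, or 17.3 ± 8.66 against 0.0266 ± 0.046 CPM (SD, n = 3). The pooled counts give a ratio of 640 (95% counting interval 177 to 5290), and the fitted log2 fold change was -9.08 (SE 0.85, adjusted p = 0.0041 by edgeR), or -11.78 without C-Gel-light replicate 1. Without that library the C-Gel-light group had 0 counts, so the size of -11.78 is set by the fit and was not measured. ENSRNOG00000030187 had 3447, 83 and 209 counts in FNI replicates 1 to 3 and 1, 0 and 0 with C-Gel-light, so 92.2% of its FNI counts came from 1 library. Its pooled ratio was 3540 (95% counting interval 635 to 140000), and its fitted log2 fold change was -11.26 (SE 2.47, adjusted p = 0.03 by edgeR). It was -8.27 without FNI replicate 1 (adjusted p = 0.011), and the call was lost without C-Gel-light replicate 1, 2 or 3 (log2 fold change -13.16, -10.81 and -10.8, adjusted p = 0.13, 0.1 and 0.08). The size of -13.16 is likewise set by the fit, since 0 counts were left in the C-Gel-light group. Over all alternatives the adjusted p of ENSRNOG00000030187 ran from 1.1e-06 to 0.21.

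**Figure D3:**
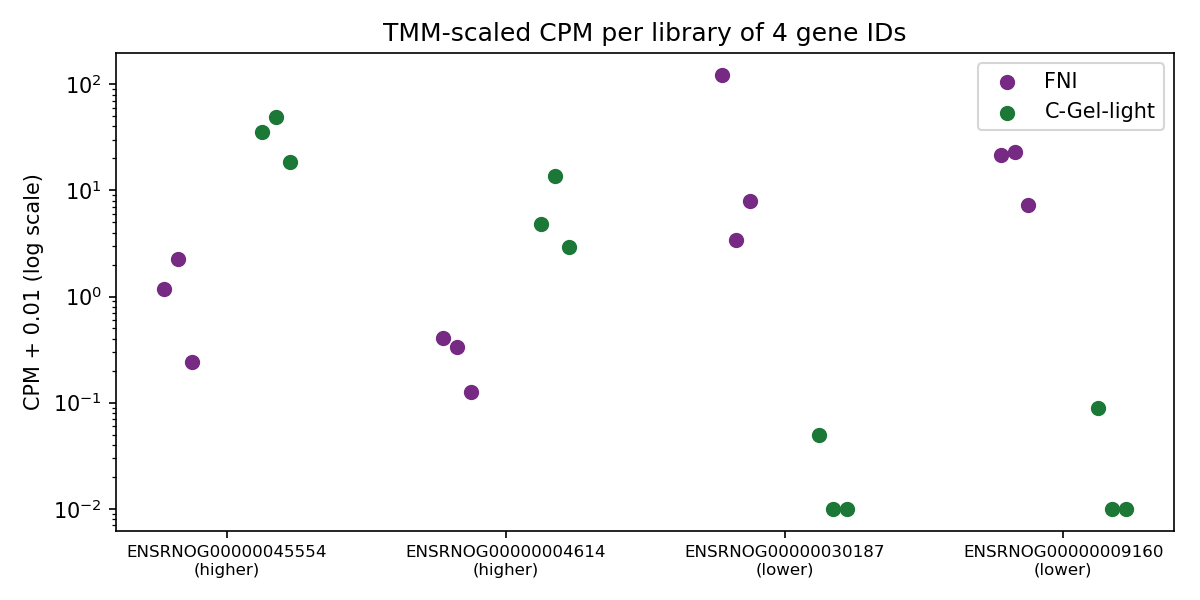
TMM-scaled CPM of the 4 gene IDs named in the text, 1 point per library, on a log axis after adding 0.01 CPM so that libraries with 0 counts can be drawn. The C-Gel-light points lie above all FNI points for the IDs marked higher and below them for the IDs marked lower, as the rule that chose the IDs required.

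A further 6 genes had 0 counts in all 3 C-Gel-light libraries and 12 to 94 counts in each FNI library. All 6 were called lower, by at least 18.2- to 61.9-fold against a limit of 3 counts over the C-Gel-light group. No gene had 0 counts in FNI with at least 10 in each C-Gel-light library. Schwann cell, macrophage, myelin and other gene lists were not analysed here, since they needed gene names.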

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

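The edgeR exact test, cyclic loess and both removals of genes were chosen after seeing the data. Against 2301 genes changed, 1101 higher and 1200 lower, DESeq2 gave 3462 genes (1836 higher, and 153 against 98 higher at least 4-fold); it kept 2290 of the 2301 and made more false calls on simulated data. An adjusted p under 0.1 gave 3876 (1909 higher, 1967 lower), an added 2-fold minimum 1024 (423 and 601), and an unadjusted p with that minimum 716 higher. Library totals gave 3937 (645 higher, 3292 lower), of which 1833 were among the 2301. FPKM is also scaled by totals: it gave 3591 (584 and 3007) with a pseudocount of 1, 3565 (574 and 2991) with 0.1, and 372 higher and 1809 lower without a filter. Genes at least 4-fold higher by FPKM then numbered 15, 40 and 14, and at least 4-fold lower 83 and 79 with a pseudocount of 1, with and without the filter, against 244; a pseudocount of 1 shrinks the folds of low genes by construction. The share of changed genes that were higher was 16.3%, 16.1% and 17.1% in these FPKM settings.

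Leaving out 1 library, which leaves fewer samples, gave 797 to 1726 genes, 335 to 864 higher and 462 to 889 lower, with 41 to 151 and 157 to 257 at least 4-fold higher and lower. Of the 2301 genes 768 to 1511 were still called, and 0 changed sign in any of these fits. That 0 was all but fixed in advance, since the values of the groups did not overlap in any of the 2301. RLE factors kept 2237, upper quartile factors 2227 and limma-voom 2150 of the 2301. The edgeR exact test gave 3111 genes, cyclic loess 2248, the removal of genes that may share reads or that vary with them 2304 and that of the 100 most abundant genes 2286. Of 88 values of the named IDs under alternatives, 80 stayed past the threshold, 8 did not and 0 changed sign. A change of sign was hardly possible, since these IDs were chosen for having no overlap between the groups. Of the 8, 7 were of ENSRNOG00000030187, and 1 was of ENSRNOG00000004614 by FPKM without a filter (adjusted p = 0.052, against 8.5e-11 to 0.044 in the other alternatives). The causes of the other shifts were not tested.

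The replicate number as a block gave 1999 genes. Libraries with the same number did not deviate together: the correlations of their deviations across genes were -0.06, 0.03 and 0.09, and 3 of 6 libraries correlated best with their own number. The tests of gene lists, with all their alternatives, and the fit without genes of other tissues were not run, since no ID matched a name. With 3 libraries per group, changes of 1.5-fold were recovered in 6% of simulated genes. The simulation changed far fewer genes than the 2301 called here, which makes the adjusted threshold stricter. Its recovery rate therefore need not hold in these data, though changes of that size may still be missed.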

Other observations

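The tests by abundance of the large falls, of an added RNA source and of the pair of IDs were chosen only after the results were seen, as were cyclic loess, the removal of abundant genes and the thresholds of the set of genes that vary together.

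The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. Only 1 of 10, the real one, gave as many as 2301 changed genes, and only 1 gave as many as 342 changed at least 4-fold. The highest other split gave 0 in both by the edgeR quasi-likelihood test, with 195 to 631 genes at an unadjusted p under 0.05 and 0 by limma-voom. The real split gave 5054 at that level, where 0.05 of the tests is 779. Each other split put libraries of both groups on each side, so the difference between groups added to the spread tested against. Few calls were therefore to be expected in those splits, and they do not show what chance gives.

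Genes that fell at least 4-fold outnumbered those that rose by 2.49 to 1, and by 2.43 to 5.09 to 1 under other scalings. Low counts alone are argued against, except in the most abundant 20% of genes. At a mean log2 CPM of 3 or more, 83 genes fell and 37 rose, a ratio of 2.24 (95% interval 1.51 to 3.4). The ratio was 2.64 (153 falls, 58 rises) in the least abundant 30% of genes and 2.78 (75 and 27) in the middle 50%. In the most abundant 20%, with 16 and 13, it was 1.23 (0.56 to 2.78) and no excess was detectable. Both intervals take genes as independent, though genes can vary together, so they are too narrow. The case against low counts therefore rests on the sizes of the ratios. A single library is argued against too, since the ratio was at least 1.7 (without FNI replicate 2) and reached 4.37 without FNI replicate 3. One RNA source added to FNI libraries in varying amount may contribute and stays open: the large falls shared 12.8% of their spread among FNI libraries, above the 2.5% reached by 95% of 1000 random sets of unchanged genes of like abundance but far from all of it, and no gene names were at hand to look for a cell type. An effect of the treatment stays open as well, and so does batch if the label held by each library alone marks one, which the labels do not say.

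Among changed genes, the share that was higher was 30 percentage points larger in the most than in the least abundant of 10 equal bins, and 47 and 48.5 points larger without C-Gel-light replicates 1 and 2, with 26.9 to 43.1 without each of the other libraries. With a library left out, the least abundant bin held only 19 to 65 changed genes. The counts taken by a few genes stay open: the gap was 29.3 points without the 100 most abundant genes, but with TMM factors their removal moved the log2 fold changes of the other genes by a median of only 0.003, so it decides nothing. Scaling cannot be told apart from a change in the tissue: the gap was 9 points with library totals but 29.6 and 29.9 with RLE and upper quartile factors. A technical trend with abundance also stays open, as cyclic loess left 12.7 points against 30.4 by limma-voom without it. The SE of the 12.7 points was 5.5 with genes taken as independent, which is too small where genes vary together. Across all tested genes the rank correlation of fold change with abundance was 0.08, and 5 of the 10 splits, the real one included, gave one as large, with 0.18 the highest other, so the tilt is weak and the splits are too few to weigh chance.

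Among gene IDs of equal length with at least 200 counts, 8 of 15328 pairs (13 IDs) had a chi-square between their counts under the 0.1 percentile of counting error, and 4 of the 8 were closer than counting error at a p under 0.05 with Bonferroni correction for the 15328 comparisons. The most abundant pair, of length 1872, had totals of 809963 and 809947. Independent counting is argued against, with a chi-square of 0.00038 over 6 libraries, and the largest difference of 8 counts in any library is consistent with reads of identical copies divided equally. This pair and the abundant genes that varied with it, 6 genes in all, held 6.35%, 1.51% and 0.82% of the counts in C-Gel-light replicates 1 to 3 and 0.65%, 0.65% and 0.31% in FNI replicates 1 to 3. Their log2 fold changes were 1.73 to 3.06, and 1 of the 6 passed the threshold (smallest adjusted p = 0.046 by edgeR). The pair had more counts in each C-Gel-light library than in any FNI library. The other genes were chosen for varying with it over all 6 libraries, so their rises were fixed by that choice.

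The series design text states 682 genes higher and 803 lower, without a threshold. None of 12 combinations of tool and threshold gave these counts. The nearest, picked after all were seen, was DESeq2 at an adjusted p under 0.05 with a 2-fold minimum, at 673 higher and 787 lower.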
